A study of Homo sapiens with 12 samples.

How the data were processed

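RNA from 12 cultures of SK-OV-3 cells, labelled as biological replicates, was measured, each on its own Affymetrix array. They formed 4 groups of 3: PBS, recombinant BMP2 (100 ng/ml), DM (5 µM) and both, all after 24 h. Per the labels' protocols, biotin-labelled cRNA was made from total RNA. Per the submitters' processing notes, the authors computed the signals with MAS5, whose version is not stated. The deposited values are 1 linear intensity per probe set on each array. The 12 arrays had trimmed means (2% trimmed) from 495.8 to 496.1, so the authors had scaled each array to a common level, and no further normalization between arrays was applied. Detection calls were not used here. The planned ratio of 3' to 5' control probe sets, a sign of RNA quality, was not analysed here. Cultures were treated as replicates, and the 3 arrays in each group limit the precision.

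Probe sets were named from a probe table: 41091 had exactly 1 gene symbol, 1801 had several and 11721 were not listed, and 0 symbols needed changing. Probe sets with 1 symbol covered 19775 genes. Signals were raised to a floor of 1 where they lay below it (396 values) and taken to log2. Each gene was represented by its probe set with the highest mean log2 value over the 12 arrays, and genes above the median of all probe sets (a signal of 69.8) were kept, which left 12674. One limma model (limma 3.58.1 in R 4.3.3) was fitted to all 12 arrays with a mean for each group, followed by empirical Bayes moderation with an intensity trend; residual degrees of freedom were 8 and prior degrees of freedom 9.24. The comparisons were BMP2 against PBS, DM against PBS, BMP2+DM against BMP2, BMP2+DM against DM, BMP2+DM against PBS, and the interaction, which is the BMP2 effect with DM minus the effect without it. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. A permutation of 3 arrays against 3 cannot give a two-sided p below 0.1, so single genes were tested by limma only.

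The gene lists, comparisons, tests, list of alternatives and the rule for naming genes were set before the data were examined. By that rule the named genes were, for each comparison of a single reagent, up to 10 with the largest rise and 10 with the largest fall among called genes whose arrays did not overlap between the groups (up to 5 each way for the interaction), all measured BMP-SMAD targets, called members of the BMP ligand, receptor and SMAD list, and up to 4 members with the smallest p of each other list described. For BMP2+DM against PBS only list members were named. Genes named outside the rule were chosen after their values were seen: these are ERBB2, PAX8 and the receptors and markers given as levels, the interaction genes given only in the closing section, and the genes of the lists added later. Of the 35 fixed lists, 31 with at least 5 measured members were tested with camera, the competitive test of limma, at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists within a comparison. Counts of list members are given both over all genes and adjusted over the list alone. The median, the mean and the camera direction had the same sign for all 38 called lists, and differed for 41 of the 148 results not called. With an estimated correlation the number of lists called went from 7 to 5 in BMP2 against PBS, 9 to 5 in DM against PBS, 10 to 9 in BMP2+DM against BMP2, 2 to 0 in BMP2+DM against DM, 3 to 2 for the interaction and 7 to 2 in BMP2+DM against PBS. Lists that are not described were not called; 4 marker lists of other cell types had too few measured members for the test and served as a check for RNA of other cells.

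The same code was tested on simulated data of 12674 genes with 200 changed, over 20 runs. In the simulated BMP2+DM against DM comparison 28.5%, 56.5% and 80.3% of genes changed by 1.5, 2 and 4-fold were recovered, with 4.20% of calls false. For the simulated interaction these shares were 9.85%, 37.1% and 68.5%, with 4.43% of calls false. With no change simulated, BMP2 against PBS gave 0.05 false calls per run. A list of 20 genes shifted by 0.5 was called in 20 of 20 runs, and 0 of 600 unshifted lists were. The simulated genes varied independently of each other, so these list results do not cover lists whose members move together. The BMP-SMAD list, for example, had an estimated correlation of 0.257.

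Alternatives tried 1 at a time were quantile normalization, median centring, log2 of the signal plus 32, no filter, the brightest 30% of probe sets, the mean of a gene's probe sets, every probe set, a variance model without a trend, a robust one, only the groups compared, a replicate block, array weights, an added 2-fold threshold, an estimated correlation, and the omission of each array in turn. The mean of a gene's probe sets took in probe sets below the filter as well. No scaling moved the median of all genes by more than 0.1 on the log2 scale. For comparisons that share arrays, unchanged groups were simulated 100 times with the same sharing. Probe sets with several symbols or none were left out of the gene tests, and genomic positions are not given.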

Results

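SK-OV-3 is an established human ovarian cancer cell line. The cells were kept for 24 h in 12 cultures, labelled as biological replicates. There were 3 with PBS, the saline control, 3 with recombinant BMP2 at 100 ng/ml, 3 with DM at 5 µM and 3 with BMP2 and DM together. BMP2 is a secreted ligand of the TGF-beta family whose receptors phosphorylate SMAD1, SMAD5 and SMAD9. DM is a compound that the labels give by these letters alone. RNA from each culture was hybridised to its own expression array, and the deposited table holds 1 MAS5 signal per probe set for each of the 12 arrays. After a filter on dim probe sets, 12674 genes were tested. The title places the experiment under BMP signalling, so the comparisons ask which genes changed with the ligand, which changed with DM, and whether DM altered the response to the ligand. Below, a gene value is a log2 fold change ± its standard error from the limma fit, with 3 arrays in each group, and a p-value is adjusted by the Benjamini-Hochberg method unless said otherwise.

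The cultures expressed genes typical of this line. ERBB2, the receptor amplified in SK-OV-3, had a geometric mean signal of 11248 over the 12 arrays, and PAX8, a transcription factor of the Müllerian lineage, had 5274. The receptors BMPR2, ACVR1 and BMPR1B were measured at 1625, 1223 and 559, and SMAD1, SMAD4 and SMAD5 at 2002, 3223 and 2519. Markers of other cell types were mostly below the filter signal of 69.8: 1 of 8 endothelial, 3 of 10 fibroblast, 1 of 9 leukocyte and 3 of 6 mesothelial genes lay above it, and 0 of these 8 were called by limma in any of the 6 comparisons, with at most 1 at an unadjusted p under 0.05. Among them were PDPN at 745, LRRN4 at 496 and COL1A1 at 328. The median signal per array ranged from 86.7 to 112. BMP2 replicate 1 stood apart, with a mean correlation of 0.934 to the other arrays of its group, the highest median signal and a score of -44.9 on the second principal component.

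Recombinant BMP2 raised the classical BMP-SMAD target genes. The ID genes encode helix-loop-helix proteins that block the DNA binding of basic helix-loop-helix factors: ID4 rose by 1.70 ± 0.16 (3.25-fold), ID3 by 1.60 ± 0.35, ID2 by 1.44 ± 0.27 and ID1 by 1.06 ± 0.14 (2.09-fold). SMAD6, an inhibitory SMAD, rose by 1.14 ± 0.20 and SMAD9 by 1.24 ± 0.21. With the mean of a gene's probe sets ID1 had 1.06, ID3 1.60, ID4 1.35, SMAD6 0.57 and SMAD9 -0.0718, and none of these was called. The call of ID3 was also lost in 4 other alternatives, among them every probe set and a robust variance, and that of ID2 with the variance model without a trend. At the same time, genes of the hypoxia and glycolysis list fell, among them ADM, which encodes the vasodilator peptide adrenomedullin, at -1.70 ± 0.27 and HK2, a hexokinase, at -1.37 ± 0.27. The chemokine receptor gene CXCR4 fell by 3.00 ± 0.37 on the log2 scale, from a signal of 1241 ± 675 (SD, n = 3) with PBS to 144 ± 27.1 with BMP2.

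Of the 14 measured BMP-SMAD targets, 7 rose in BMP2 against PBS, none fell and 7 were not called, with 8 rising when adjusted over the list alone. HEY1, a transcriptional repressor, was the seventh, at 0.56 ± 0.10. SMAD7, the other inhibitory SMAD, had 0.71 ± 0.17 with an adjusted p of 0.0818, and BAMBI, MSX1, MSX2, ATOH8, HEYL and SMURF1 had values from 0.10 to 1.23 that were not called. The list's median was 0.89, with an adjusted p of 5.01e-15 by camera, limma's competitive test of gene lists, and adjusted p = 0.0228 with an estimated correlation. BMP2 replicate 2 had a mean list score of 0.50 above the PBS arrays, against 1.02 and 1.01 for replicates 1 and 3. Among the 13 genes of the BMP ligands, receptors and SMADs list, 0 were called by limma, 1 had an unadjusted p under 0.05, and the list was not called (adjusted p = 0.747).

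**Figure D1:**
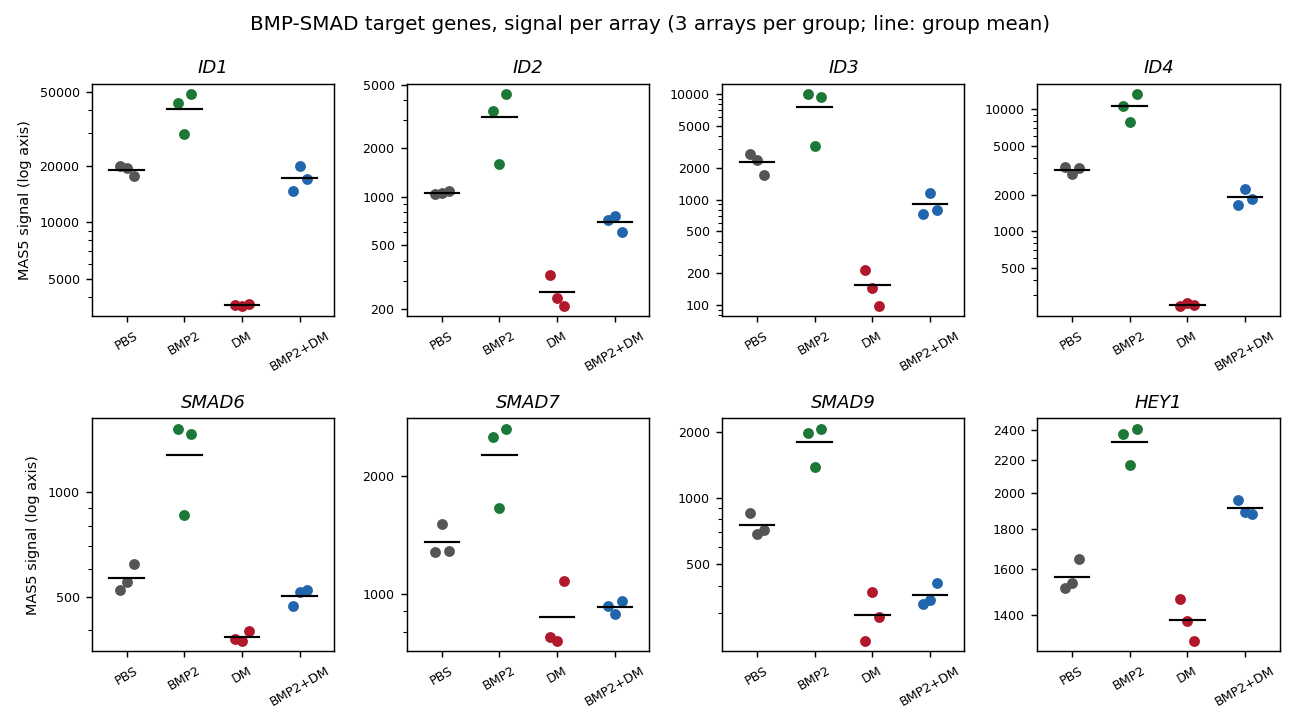
MAS5 signal on a log axis for 8 BMP-SMAD target genes in the 4 groups; each point is 1 array and each black line the mean of 3 arrays. ID1, ID3 and ID4 are highest with BMP2, lowest with DM alone and in between with both, as in ID4, whose mean signal was 3192 with PBS, 10609 with BMP2, 250 with DM and 1910 with both.

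Other groups also moved with BMP2. Of 13 measured TGF-beta targets, 3 rose (6 adjusted over the list alone), none fell and 10 were not called; TGFBI, a secreted matrix protein, rose by 0.91 ± 0.09, PMEPA1, a feedback inhibitor of TGF-beta signalling, by 0.56 ± 0.12 and TPM1, a tropomyosin, by 0.54 ± 0.08. That list had an adjusted p of 3.19e-07 by camera and adjusted p = 0.0136 with an estimated correlation. Of 14 measured cholesterol synthesis genes, 2 rose (9 adjusted over the list alone), none fell and all 14 had positive values: IDI1, the isopentenyl diphosphate isomerase, rose by 0.83 ± 0.13 and MSMO1, a sterol oxidase, by 0.40 ± 0.09. IDI1 had 0.12 and was not called with the mean of its probe sets. The call of MSMO1 was lost in 7 alternatives and that of PMEPA1 in 6, a replicate block and median centring among both. The list's adjusted p was 4.15e-10, and adjusted p = 0.0034 with an estimated correlation. In the mesenchymal list 1 of 14 rose (1 adjusted over the list alone), SNAI2, a repressor of E-cadherin, by 0.88 ± 0.13. The mesenchymal call (adjusted p = 0.00387) was lost with an estimated correlation (adjusted p = 0.0717) and without BMP2 replicate 1 (adjusted p = 0.0863, in a range of 0.000761 to 0.0863 over 16 alternatives: the scalings, the offset, the block and each array omitted). No member of the mitosis list was called by limma (5 of 20 at an unadjusted p under 0.05, 2 adjusted over the list alone, all higher), although the list as a whole lay higher, with a median of 0.15 and an adjusted p of 0.000488, a call lost with an estimated correlation (adjusted p = 0.0694). The median of the mitosis list ran from 0.0757 to 0.172 over the 16 alternatives.

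Of the 20 measured hypoxia and glycolysis genes, 5 fell with BMP2 (12 adjusted over the list alone), none rose and 15 were not called. Beside ADM and HK2, NDRG1, a stress-induced gene, fell by 1.42 ± 0.17 on the log2 scale, BNIP3, a mitophagy receptor, by 0.95 ± 0.14 and VEGFA, the endothelial growth factor, by 0.68 ± 0.13. The median was -0.42, with an adjusted p of 8.09e-14 and adjusted p = 0.0302 with an estimated correlation. BMP2 replicate 1, the array that stood apart, had the lowest mean score of this list, -0.88 against -0.37 and -0.51 for replicates 2 and 3; without it the median was -0.31, 3 genes fell and the adjusted p was 1.45e-10, in a range of 1.94e-16 to 1.89e-10 over the 16 alternatives. The MAPK immediate early and feedback list lay lower (median -0.15, adjusted p = 5e-04, and adjusted p = 0.0228 with an estimated correlation), with 0 of 18 members called by limma, 6 lower at an unadjusted p under 0.05 and 3 adjusted over the list alone. STC1, which encodes the glycoprotein hormone stanniocalcin-1, fell by 1.47 ± 0.13, GJB2, a gap junction protein, by 1.37 ± 0.28 and ADGRF1, an adhesion G protein-coupled receptor, had -1.10 ± 0.17. Larger falls were fitted for DECR2, CACNG4 and KRT9 at -1.96 ± 0.39, -1.92 ± 0.39 and -2.36 ± 0.50. ITPKB was called higher from a PBS signal of 14.6 ± 10.7, below the filter, so no fold change is given, and its call was lost with the mean of its probe sets and with only the groups compared. CASTOR2, SLC35C1 and the long noncoding RNA UCA1 rose by 1.86 ± 0.38, 1.38 ± 0.28 and 1.13 ± 0.16, with SLC35C1 at 0.30 and not called when the mean of its probe sets was used.

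In total limma called 80 genes in BMP2 against PBS, 41 higher and 39 lower, of which 25 changed at least 2-fold; 1328 genes had an unadjusted p under 0.05 where 634 would be expected by chance. Centring each array on its median called 50, 17 of them higher, the mean of a gene's probe sets 10 and a variance model without a trend 12, of which 48, 9 and 11 were among the 80. The count fell to 36 without PBS replicate 3, 39 without BMP2 replicate 3, 40 without PBS replicate 1, 40 without BMP2 replicate 1 and 46 without PBS replicate 2. Of 29 called genes followed singly, CXCR4, STC1 and TGFBI kept the call in each of the alternatives, up to 12, that tested them, and 26 lost it in at least 1. All of the 26 but DECR2 lost it with the mean of a gene's probe sets or the variance model without a trend, HEY1, TPM1, IDI1, MSMO1, PMEPA1 and SLC35C1 also with median centring, and GJB2, MSMO1 and PMEPA1 with a replicate block.

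DM alone lowered the ID genes, the opposite of their change with BMP2. ID3 fell 15.1-fold (-3.91 ± 0.35), ID4 12.8-fold (-3.67 ± 0.16), ID1 5.25-fold (-2.39 ± 0.14) and ID2 4.22-fold (-2.08 ± 0.27) against PBS. ID4 signal went from 3192 ± 219 (SD, n = 3) to 250 ± 6.41. In the same cultures, genes of the amino acid response controlled by the transcription factor ATF4 rose, led by NUPR1, a stress-induced chromatin protein, at 2.75 ± 0.23, and ASNS, asparagine synthetase, at 2.61 ± 0.13. With the mean of its probe sets ASNS had 1.27 and was not called. DUSP4, a phosphatase that acts on MAP kinases, rose 5.50-fold and EGR1, an immediate early transcription factor, 3.67-fold.

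Of the 14 BMP-SMAD targets, 6 fell with DM (7 adjusted over the list alone), 1 rose (1 adjusted over the list alone) and 7 were not called. Besides the ID genes, SMAD9 fell by 1.37 ± 0.21 and SMAD7 by 0.65 ± 0.17, while the homeobox gene MSX1 rose by 0.83 ± 0.16. SMAD6 had -0.56 ± 0.20 with an adjusted p of 0.156. The list's median was -0.40 with an adjusted p of 5.73e-08; this call was lost with an estimated correlation (adjusted p = 0.0654). Of 13 TGF-beta targets 3 fell (4 adjusted over the list alone) and none rose: TGFBI fell by 1.24 ± 0.09, TAGLN, an actin-binding protein, by 1.09 ± 0.22 and TPM1 by 0.77 ± 0.08, or 0.44 and not called with the mean of its probe sets. Their list had an adjusted p of 2.87e-05, and adjusted p = 0.0308 with an estimated correlation. In the extracellular matrix list 2 of 15 fell (6 fell and 1 rose adjusted over the list alone), MMP1, the interstitial collagenase, by 0.96 ± 0.09 and THBS1, thrombospondin 1, by 1.10 ± 0.28; the calls of THBS1 and SMAD7 were each lost in 5 alternatives, median centring among them, and those of SMAD9, MSX1 and TAGLN with the mean of a gene's probe sets. The matrix list's adjusted p of 0.0113 became adjusted p = 0.0635 with an estimated correlation.

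All 23 measured members of the ATF4 amino acid response list had positive values with DM, 12 of them called (14 adjusted over the list alone). ATF4 itself rose by 1.31 ± 0.11, CHAC1, a glutathione-degrading enzyme, by 2.51 ± 0.55, and PHGDH and PSAT1, the first enzymes of serine synthesis, by 1.96 ± 0.20 and 1.63 ± 0.09. The median was 0.71, with an adjusted p of 5.05e-22 by camera and adjusted p = 0.00169 with an estimated correlation. The mean score of this list was 1.01 ± 0.0836 (SD, n = 3) above PBS with DM and 1.03 ± 0.0847 with both reagents, and -0.01 ± 0.0597 with BMP2 alone. Of 18 MAPK immediate early and feedback genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with DUSP4 at 2.46 ± 0.19, EGR1 at 1.88 ± 0.17, DUSP6, a phosphatase of ERK, at 1.03 ± 0.15 and SPRY2, a feedback inhibitor of receptor tyrosine kinases, at 0.88 ± 0.14. The adjusted p was 8.91e-08, and adjusted p = 0.00413 with an estimated correlation. Of 17 NF-kB and cytokine genes 6 rose (7 adjusted over the list alone) and none fell: the cytokine IL6 by 1.24 ± 0.13, the chemokine CXCL8 by 0.84 ± 0.08, IL1A by 0.71 ± 0.11 (0.29 and not called with the mean of its probe sets) and LIF by 0.70 ± 0.15. CHAC1, DUSP6 and CXCL8 were not called with the mean of their probe sets. The NF-kB list had an adjusted p of 1.69e-07, and adjusted p = 0.0331 with an estimated correlation.

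**Figure D2:**
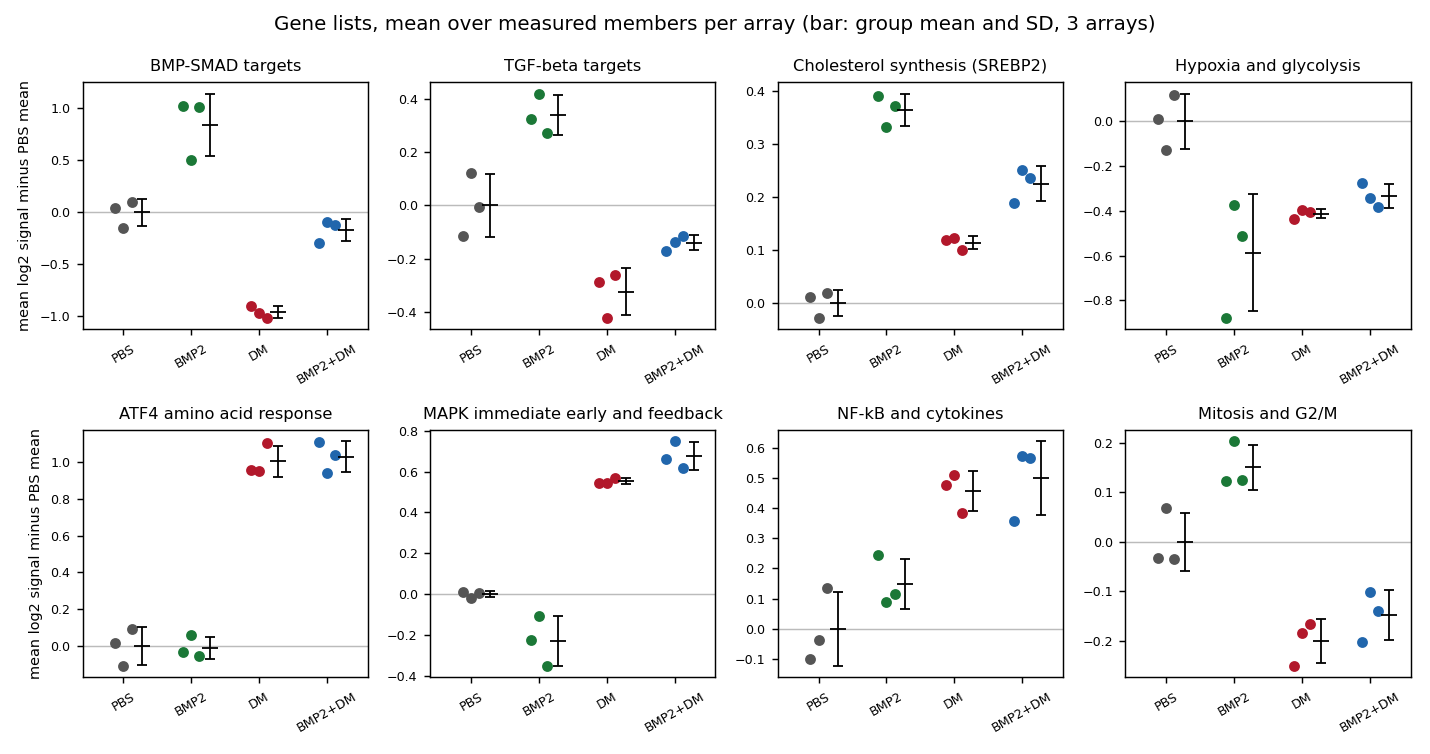
Mean log2 signal over the measured members of 8 gene lists on each array, relative to the mean of the PBS arrays; points are arrays and bars the group mean with its SD over 3 arrays. The ATF4 list is near 0 with PBS and BMP2 and near 1 in both groups with DM, and the BMP-SMAD list has means of 0.84 with BMP2, -0.96 with DM and -0.17 with both.

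Cell division genes were lower with DM. Of 20 mitosis and G2/M genes 6 fell (7 adjusted over the list alone) and none rose, with KIF20A, a mitotic kinesin, at -0.59 ± 0.12, BIRC5, survivin, at -0.41 ± 0.08, HMMR at -0.39 ± 0.10 and NUSAP1 at -0.36 ± 0.08. The list had a median of -0.22, an adjusted p of 4.51e-06 and adjusted p = 0.0331 with an estimated correlation. Of 20 DNA replication and G1/S genes 2 fell (5 adjusted over the list alone), UHRF1, a reader of hemimethylated DNA, by 0.72 ± 0.09 and MCM4, a subunit of the replicative helicase, by 0.52 ± 0.13; the adjusted p of 2.52e-05 became adjusted p = 0.0635 with an estimated correlation. The calls of KIF20A, BIRC5, HMMR, NUSAP1 and MCM4 were lost with median centring and with the variance model without a trend. Of the 20 hypoxia and glycolysis genes 4 fell (8 adjusted over the list alone) and none rose: ADM by 1.83 ± 0.27, PFKFB3, a regulator of glycolytic flux, by 0.88 ± 0.15, PDK1, a pyruvate dehydrogenase kinase, by 0.61 ± 0.16 and P4HA1, a prolyl hydroxylase subunit, by 0.47 ± 0.13. That call (adjusted p = 5.73e-08) was lost with an estimated correlation (adjusted p = 0.0719), and P4HA1 had 0.15 when the mean of its probe sets was used, where BIRC5 had -0.15, DEPP1 -1.79 and none of the 3 was called. Median centring also ended the calls of P4HA1 and PDK1. Among the other genes with the largest changes, IL20RB, a cytokine receptor subunit, rose by 1.58 ± 0.38 and DEPP1 fell by 2.77 ± 0.62. ITPKB, CYP24A1, NRG1, C1orf167, ARID5A, GRIN2B, PRPF40B and COL8A1 had fitted changes of more than 2 but a mean signal below the filter in at least 1 group.

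The total was 453 genes in DM against PBS, 236 higher and 217 lower by limma, with 84 changed at least 2-fold and 2052 at an unadjusted p under 0.05. Median centring called 234, of which 151 were higher, the mean of a gene's probe sets 104 and the variance model without a trend 227, with 232, 94 and 206 among the 453. Without PBS replicate 3 it was 252, without DM replicate 1 260 and without PBS replicate 1 295. Of 46 called genes followed singly, 19 kept the call in each of the alternatives, up to 12, that tested them, among them ID1, ID2, ID3, ID4, ATF4, NUPR1, PHGDH, PSAT1, DUSP4, EGR1 and IL6, and 27 lost it in at least 1.

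Added to BMP2, DM lowered the ID genes and SMAD9 from their raised level. In BMP2+DM against BMP2, ID3 had -2.92 ± 0.35 (7.58-fold lower), ID4 -2.45 ± 0.16, SMAD9 -2.30 ± 0.21, ID2 -2.06 ± 0.27 and ID1 -1.21 ± 0.14, all called; SMAD9 had -1.29 and was not called with the mean of its probe sets. TGFBI fell 3.70-fold, UCA1 4.96-fold and GASK1B, a Golgi-associated kinase-like protein, 8.78-fold. NUPR1 rose 9.21-fold, the immediate early factors FOS and EGR1 rose 8.38-fold and 6.46-fold, and TRIB3, a pseudokinase induced by ATF4, rose 3.90-fold.

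Of the 14 BMP-SMAD targets, 7 fell and 1 rose (8 and 1 adjusted over the list alone) in this comparison, with SMAD6 at -1.31 ± 0.20, SMAD7 at -1.26 ± 0.17 and MSX1 at 0.74 ± 0.16. With the mean of their probe sets SMAD6 had -0.23 and TAGLN, a TGF-beta target, -0.43, neither called. The median was -0.86, with an adjusted p of 9.26e-10 and adjusted p = 0.0453 with an estimated correlation. In the list of BMP ligands, receptors and SMADs 1 of 13 fell (1 adjusted over the list alone), SMAD5 at -0.52 ± 0.11, and the list was not called (adjusted p = 0.171). Of 13 TGF-beta targets 4 fell (8 adjusted over the list alone), among them TPM1 at -1.11 ± 0.08, SKIL, a SMAD co-repressor, at -1.06 ± 0.15 and TAGLN at -0.83 ± 0.22. Of 14 mesenchymal genes 6 fell and 1 rose (6 and 1 adjusted over the list alone): FN1, fibronectin, fell by 0.97 ± 0.15, SNAI2 by 0.89 ± 0.13, SPARC by 0.53 ± 0.13 and VIM, vimentin, by 0.51 ± 0.11. The calls of SMAD5 and SPARC were lost with median centring, and those of MSX1, TPM1, SKIL, SPARC and VIM with the mean of a gene's probe sets. The TGF-beta list had an adjusted p of 3.15e-06 (adjusted p = 0.0117 with an estimated correlation) and the mesenchymal list 0.000677 (adjusted p = 0.0453 with an estimated correlation).

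With BMP2 present, 13 of 23 ATF4 list genes rose with DM and none fell (17 and 0 adjusted over the list alone), with ASNS at 2.26 ± 0.13 and PSAT1 at 1.60 ± 0.09. With the mean of its probe sets ASNS had 0.0995 and was not called. Of 18 MAPK immediate early and feedback genes 12 rose and none fell (15 and 1 adjusted over the list alone), with DUSP4 at 1.72 ± 0.19, DUSP6 at 1.41 ± 0.15 and PHLDA1 at 0.72 ± 0.07. Of 17 NF-kB and cytokine genes 7 rose and none fell (9 and 0 adjusted over the list alone), with IL6 at 1.40 ± 0.13, IL1A at 0.84 ± 0.11, CCL20 at 0.82 ± 0.10 and CXCL8 at 0.67 ± 0.08; IL1A had -0.59 when the mean of its probe sets was used, where CXCL8 was not called. By camera the ATF4, MAPK and NF-kB lists had adjusted p of 4.55e-19, 9.34e-14 and 9.4e-06, and adjusted p = 0.00141, 0.000911 and 0.0453 with an estimated correlation.

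Of 20 mitosis genes 9 fell with DM on top of BMP2 and none rose (13 and 0 adjusted over the list alone), with KIF11, the spindle kinesin Eg5, at -0.61 ± 0.11, HMMR at -0.55 ± 0.10, NUSAP1 at -0.40 ± 0.08 and BIRC5 at -0.38 ± 0.08. Of 20 DNA replication and G1/S genes 3 fell and 1 rose (7 and 1 adjusted over the list alone): CDT1, a licensing factor, fell by 0.70 ± 0.15, UHRF1 by 0.48 ± 0.09 and RRM1, a ribonucleotide reductase subunit, by 0.33 ± 0.08, and MCM2 rose by 0.43 ± 0.10. Of 14 cholesterol synthesis genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with HSD17B7 at -0.57 ± 0.11, SC5D at -0.55 ± 0.10, HMGCS1 at -0.52 ± 0.12 and IDI1 at -0.49 ± 0.13. Of 11 heat shock genes 3 fell (3 adjusted over the list alone), HSP90AA1 at -0.47 ± 0.11, HSPB1 at -0.47 ± 0.13 and HSPD1 at -0.37 ± 0.08, while HSPD1 had 0.14 with the mean of its probe sets and -0.18 with quantile normalization. BIRC5 had -0.15 and IDI1 -0.83 with the mean of their probe sets, neither called. The mitosis list had an adjusted p of 5.17e-09 and the cholesterol list 0.00668, with adjusted p = 0.0117 and 0.0453 with an estimated correlation. The DNA replication call (adjusted p = 0.000746) was lost with an estimated correlation (adjusted p = 0.104), and the heat shock call (adjusted p = 0.00784, and adjusted p = 0.0476 with an estimated correlation) was lost with quantile normalization (adjusted p = 0.0627, in a range of 0.00464 to 0.0627 over the 16 alternatives). The calls of KIF11, NUSAP1, BIRC5, CDT1, UHRF1, RRM1, MCM2, HSD17B7, HMGCS1, IDI1, HSPB1 and HSPD1 were lost with median centring, that of SC5D with the mean of its probe sets and that of HSP90AA1 with the variance model without a trend. ANGPT2, angiopoietin 2, rose by 2.85 ± 0.63 and SERINC2 by 2.67 ± 0.66, calls also lost without the trend. AMACR, CACNA2D3, GLP1R, JCAD, LOC101927330, MIP, MOS, NPAS1 and TMEM163 were also among the genes with the largest changes but had a mean signal below the filter in at least 1 group.

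DM changed 919 genes in the presence of BMP2, 517 higher and 402 lower by limma, 153 of them at least 2-fold, and 2757 had an unadjusted p under 0.05. Median centring called 517, of which 377 were higher and 505 among the 919; the mean of a gene's probe sets gave 275 and the variance model without a trend 455, with 233 and 438 among the 919. It was 553, 580 and 611 without BMP2+DM replicates 2, 3 and 1, and 608 without BMP2 replicate 3. Of 59 called genes followed singly, 23 kept the call in each of the alternatives, up to 12, that tested them, among them ID1, ID2, ID3, ID4, SMAD7, TGFBI, NUPR1, TRIB3, FOS and EGR1, and 36 lost it in at least 1.

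BMP2 added to DM raised few genes, and 3 of the 6 called were ID genes. ID4 rose by 2.92 ± 0.16 (7.59-fold), ID3 by 2.59 ± 0.35 (6.01-fold) and ID1 by 2.25 ± 0.14 (4.74-fold) in BMP2+DM against DM. ID1 signal was 3613 ± 37.4 (SD, n = 3) with DM and 17275 ± 2695 with both, beside 19004 ± 1248 with PBS. MT1H, a metallothionein, rose by 0.70 ± 0.11 and APLP2, a relative of the amyloid precursor protein, by 0.54 ± 0.09; 5 of the 7 other APLP2 probe sets had the same sign. With the mean of a gene's probe sets ID4 had 1.74 and APLP2 0.25, neither called. Of the 6 genes only ID1 kept its call in each of the alternatives that tested it; MT1H and APLP2 lost theirs with median centring as well. RESF1 was the gene that fell, by 0.63 ± 0.10.

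Of the 14 BMP-SMAD targets, 3 rose (5 adjusted over the list alone), none fell and 11 were not called. ID2 had 1.45 ± 0.27 with an adjusted p of 0.0618, HEY1 0.47 ± 0.10, SMAD6 0.39 ± 0.20, SMAD9 0.31 ± 0.21 and SMAD7 0.11 ± 0.17. The list's median was 0.31 with an adjusted p of 7.67e-10, a call that was lost with an estimated correlation (adjusted p = 0.22). Over the 16 alternatives this median ran from 0.184 to 0.384. No TGF-beta target was called by limma (5 of 13 higher at an unadjusted p under 0.05, 1 adjusted over the list alone), with TGFBI at 0.26 ± 0.09 and PMEPA1 at 0.43 ± 0.12. The TGF-beta list had a median of 0.19 and an adjusted p of 0.0136, lost with an estimated correlation (adjusted p = 0.22), with median centring (adjusted p = 0.0627), without DM replicate 2 (adjusted p = 0.057) and without BMP2+DM replicate 3 (adjusted p = 0.0579), in a range of 0.00824 to 0.0627 over the 16 alternatives. In the 6 targets whose fall with DM was called, BMP2 brought back 93.8% of the fall in ID1, 79.6% in ID4, 70.0% in ID2, 66.1% in ID3, 22.8% in SMAD9 and 16.0% in SMAD7, as ratios of the fitted log2 changes, and the rises of ID2, SMAD9 and SMAD7 were not called. Both changes in each ratio use the DM arrays with opposite sign, which ties them together without any effect. Where the fall was not called, the ratios divide by a change not told from 0 and measure no recovery. They were 257% in HEY1, 70.6% in SMAD6, 37.1% in ATOH8, 4.36% in MSX2 and -2.53% in SMURF1.

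Of the 6 genes called in BMP2+DM against DM by limma, 5 were higher and 1 lower, 3 changed at least 2-fold, and 1125 genes had an unadjusted p under 0.05. Median centring also called 6, with 4 higher and 4 among the 6 as reported; the mean of a gene's probe sets called 1, the variance model without a trend 2, array weights 14 and a test of every probe set 13. Without DM replicate 2 there were 3, and without BMP2+DM replicate 1 there were 21.

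The response to BMP2 differed with and without DM for 15 genes by the interaction test. CXCR4, at -3.00 ± 0.37 with BMP2 alone, had 0.30 with BMP2 on top of DM, a difference of 3.30 ± 0.52. CXCR4 signal was also lower than PBS with DM alone and with both, so the difference does not show that DM prevented the fall. STC1 went from -1.47 to -0.22 (difference 1.25 ± 0.18), NDRG1 from -1.42 to -0.01 (1.41 ± 0.25) and IGFBP3, a binding protein of insulin-like growth factors, from -0.78 to 0.45 (1.23 ± 0.20). CD24, a surface glycoprotein, had 0.68 without and -0.33 with DM (-1.01 ± 0.13). On the log2 scale ID1 and ID4 had a larger BMP2 effect in the presence of DM, from a level that DM had lowered. The effect was 1.06 without and 2.25 with DM for ID1 (difference 1.18 ± 0.20), and 1.70 and 2.92 for ID4 (1.22 ± 0.22). With both reagents ID1 and ID4 stood at -0.15 and -0.75 against PBS, so neither rose above its PBS level. Of the 10 called genes followed singly, DECR2 kept the call in each of the alternatives that tested it and 9 lost it in at least 1. All 9, CXCR4, STC1, NDRG1, IGFBP3, CD24, ID1, ID4, BNIP3 and SF3B1, lost it with the mean of a gene's probe sets (0.40 for ID4, -0.68 for CD24) and with the variance model without a trend. All but CXCR4 lost it with median centring, and ID1, ID4, BNIP3 and SF3B1 with a replicate block. Each replicate number holds 1 array of each group, so the block can change the errors but not the fitted values.

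Of the 20 hypoxia and glycolysis genes, 2 had a positive interaction, NDRG1 and BNIP3 (1.09 ± 0.20), and 13 when adjusted over the list alone; ADM had 1.87 ± 0.38 with an adjusted p of 0.0673 and HK2 1.68 ± 0.39 with 0.139. The list's median difference was 0.53 with an adjusted p of 4.33e-11, lost with an estimated correlation (adjusted p = 0.0851). This list also had lower medians than PBS with DM alone and with both, so the difference does not show that DM prevented the fall. No cholesterol synthesis gene was called by limma (7 of 14 lower at an unadjusted p under 0.05, 5 adjusted over the list alone), and the list's median difference was -0.28, with an adjusted p of 3.47e-05 and adjusted p = 0.0314 with an estimated correlation. IDI1, at 0.83 without DM, had a difference of -0.74 ± 0.19. No MAPK list gene was called by limma (6 higher and 1 lower of 18 at an unadjusted p under 0.05, 5 and 1 adjusted over the list alone), with FOS at 2.26 ± 0.64 and FOSL1 at 0.76 ± 0.19. The MAPK list's median difference was 0.30, with an adjusted p of 0.000443 and adjusted p = 0.0342 with an estimated correlation. The BMP-SMAD list had 2 higher and 0 lower of 14 (2 and 1 adjusted over the list alone), a median of -0.13 and an adjusted p of 0.922.

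**Figure D3:**
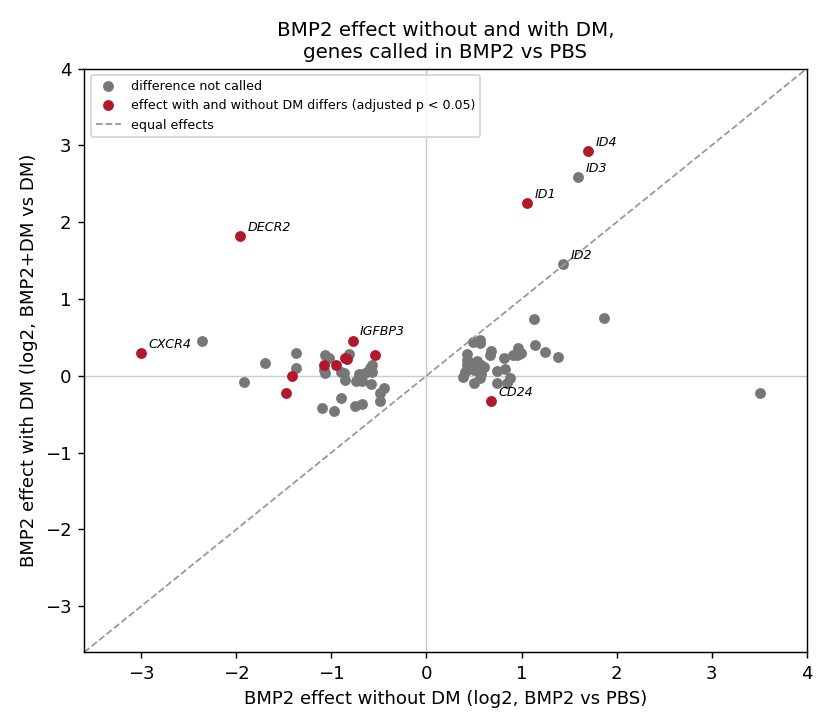
Log2 fold change with BMP2 in the presence of DM against the change without DM for the 80 genes called in BMP2 against PBS; red points are genes whose 2 effects differed by the interaction test, and the dashed line marks equal effects. ID1 and ID4 lie above the line with 2.25 and 2.92 on the vertical axis, and CXCR4, at -3.00 without DM, lies at 0.30.

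Across the 80 genes called with BMP2 alone, the slope of the effect with DM on the effect without it was 0.138, with a standard error of 0.0616 from the spread across genes, and 48 of the 80 kept their sign. These comparisons share no arrays, but genes are not independent replicates, so no p-value is given. The genes were chosen for their effect without DM, which inflates that effect and pulls the slope down even where the response is unchanged. No slope for an unchanged response was simulated, so this slope alone does not show that DM weakened the response. ID1, ID3 and ID4 were called in both. The slope was 0.0406 without BMP2 replicate 2, 0.0653 without BMP2+DM replicate 3 and 0.270 without PBS replicate 3. For the effect of DM, of 453 genes called in DM against PBS, 427 had the same sign in BMP2+DM against BMP2, 241 were called in both and 239 of these moved the same way, with a slope of 0.589. This slope is pulled down by the choice of genes as well.

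By limma 13 interaction values were positive and 2 negative, 12 of the 15 were at least 2-fold, and 1103 genes had an unadjusted p under 0.05. This count rested on few arrays: it was 0 without PBS replicate 3 (931 at an unadjusted p under 0.05), 4 without PBS replicate 1, 7 without PBS replicate 2, 9 without BMP2 replicate 1, 42 without BMP2 replicate 2, 6 without DM replicate 1, 8 without DM replicate 2, and 9, 5 and 5 without BMP2+DM replicates 1, 2 and 3. With median centring 2 genes remained past the threshold, both higher, and the mean of a gene's probe sets or the variance model without a trend left 1, a replicate block gave 8, of which 7 were among the 15, and array weights gave 31.

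Cells given both reagents still differed from PBS in part of the groups that moved with DM. ASNS was higher by 2.59 ± 0.13, NUPR1 by 2.77 ± 0.23, EGR1 by 2.25 ± 0.17 and IL6 by 1.35 ± 0.13. The ID genes lay closer to their PBS level: ID1 had -0.15 ± 0.14 (adjusted p = 0.643) and ID2 -0.62 ± 0.27 (adjusted p = 0.208), while ID3 was lower by -1.33 ± 0.35 and ID4 by -0.75 ± 0.16. SMAD9 was lower by -1.06 ± 0.21 and MSX1 higher by 0.84 ± 0.16.

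Of the 14 BMP-SMAD targets, 3 were lower and 1 higher (4 and 3 adjusted over the list alone), and the list was not called (median -0.16, adjusted p = 0.121). The TGF-beta and extracellular matrix lists, both lower with DM alone, were not called either (medians 0.04 and -0.11, adjusted p = 0.0595 and 0.0783), although 3 of 13 and 2 of 15 members were lower as with DM alone (4 lower and 1 higher, and 2 lower, adjusted over the list alone). The TGF-beta list's mean of -0.14 and its test pointed down, against its median. Higher were 12 of 23 ATF4 list genes (19 adjusted over the list alone), 9 of 18 MAPK genes with 1 lower (12 and 1 adjusted over the list alone) and 5 of 17 NF-kB genes (9 adjusted over the list alone). The ATF4 and MAPK lists had adjusted p of 8.45e-21 and 4.97e-10, and adjusted p = 0.00145 for each with an estimated correlation; the NF-kB call (adjusted p = 2.27e-07) was lost with it (adjusted p = 0.0532). Lower were ADM of the 20 hypoxia genes (5 adjusted over the list alone), UHRF1 and CDT1 of the 20 DNA replication genes (2 adjusted over the list alone) and NUSAP1 of the 20 mitosis genes (5 adjusted over the list alone). These lists had adjusted p of 3.95e-06, 0.000139 and 0.000273, all lost with an estimated correlation (adjusted p = 0.17, 0.101 and 0.0752). Of 16 ER chaperone genes, HERPUD1 was higher and HSP90B1 lower (5 and 1 adjusted over the list alone), and the call of a higher list (adjusted p = 0.0117) was lost with an estimated correlation (adjusted p = 0.0752), with median centring (adjusted p = 0.0513) and without PBS replicate 3 (adjusted p = 0.0684), in a range of 0.00357 to 0.0684 over the 16 alternatives. In total 519 genes were called by limma, 305 higher and 214 lower, with 73 at least 2-fold and 2367 at an unadjusted p under 0.05. Median centring called 221, all among the 519, the mean of a gene's probe sets 119 and the variance model without a trend 238, with 97 and 215 among the 519, and array weights and a test of every probe set gave 828 and 958. It was 269 and 277 without BMP2+DM replicates 3 and 2, and 320, 342 and 343 without PBS replicates 3, 1 and 2.

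Several of these comparisons share arrays, which ties their values together without any effect. BMP2 against PBS and BMP2+DM against BMP2 share the BMP2 arrays: 74 of the 80 genes had opposite signs, and all 49 called in both moved in opposite directions. The correlation across all genes was -0.533, where unchanged groups simulated with the same shared arrays gave -0.50, and the covariance was -0.114 against -0.0687, a difference of -0.0450. Of the 80 genes 7.50% had the same sign, beside 4.04% simulated; a share this close to 0 without any change cannot show a further effect or exclude one. Higher and then lower were 27 genes, against 1.30 for independent lists, and lower and then higher 22 against 1.59, but independent lists leave the shared arrays out of account. BMP2 against PBS and DM against PBS share the PBS arrays: the correlation was 0.340 against a simulated 0.50, and the covariance differed from the simulated one by -0.00142. Of the 80 genes 52.5% had the same sign, against 96.1% simulated. The simulated share is from genes without any effect, so it is no measure for genes that BMP2 changed. In this pair 14 genes, ID1 among them, were higher with BMP2 and lower with DM (0.702 for independent lists), 4 lower and then higher (0.726), 4 higher in both (0.763) and 7 lower in both (0.668). The 3 arrays of a control group cannot be divided into parts of at least 2, so part of the opposite signs in the first pair and of the common signs in the second may come from the shared arrays.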

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

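Chosen only after the results were seen were the permutation of residuals for the interaction, the test of the ATF4 list against the ID genes and the test of whether the PBS arrays stand apart; the other tests here were planned or written down first.

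The effect of BMP2 differed with and without DM, by limma's interaction test, for 15 genes, whose differences are given as the effect with DM minus the effect without. CXCR4 differed by 3.30 (adjusted p = 0.0205) and DECR2 by 3.78 (adjusted p = 0.011), the latter from -1.96 to 1.82. STC1 differed by 1.25 (adjusted p = 0.011), NDRG1 by 1.41, BNIP3 by 1.09 and PHLDA2 by 1.09, all lower with BMP2 alone. IGFBP3 differed by 1.23, PDZK1IP1 by 1.21, RNASET2 by 1.05, ARF5 by 0.98 and the chemokine CCL20 by 0.81. ID1 differed by 1.18 and ID4 by 1.22, both higher in each setting. CD24 differed by -1.01 (adjusted p = 0.00874) and the splicing factor SF3B1 by -0.55 (adjusted p = 0.0486). Of these, 13 were among the 80 genes called in BMP2 against PBS. The interaction uses the BMP2 and PBS arrays with their sign turned, so part of this overlap can come from the shared arrays alone. No value without any change was simulated for this pair. In 1 of 100 groupings of the 12 arrays into 4 groups of 3, the real one, were as many as 15 genes called, and the highest of the others was 2. These groupings exclude nothing, because they put the effect of DM itself into the residual variance. With the effects of BMP2 and DM kept, the residuals of the additive fit were permuted over the arrays. The real arrangement, 1 of 100, reached 15 and the highest of the others was 4. Permuted residuals thus rarely gave such a count, but this does not exclude that single arrays gave it. Without PBS replicate 3 no gene was called by limma (931 at an unadjusted p under 0.05), and without BMP2 replicate 2 there were 42; a replicate block called 8, of which 7 were among the 15, and the calls lost included ID1, ID4, BNIP3 and SF3B1. Median centring called 2, and the mean of a gene's probe sets and the variance model without a trend 1 each. At the level of lists the median difference was 0.53 for hypoxia and glycolysis (adjusted p = 4.33e-11, lost with an estimated correlation at 0.0851), 0.30 for the MAPK list (adjusted p = 0.000443) and -0.28 for cholesterol synthesis (adjusted p = 3.47e-05).

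For each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. In each the real split, 1 of the 10, gave the most genes: 80 for BMP2 against PBS with 1 as the highest other, 453 for DM against PBS with 0, 919 for BMP2+DM against BMP2 with 0, 6 for BMP2+DM against DM with 1, and 519 for BMP2+DM against PBS with 0. Every other split mixes arrays of both groups, which puts the effect itself into the residual variance, so these counts exclude nothing.

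The ATF4 amino acid response list was higher with DM whether or not BMP2 was given. Neither array scaling nor a single array accounts for the whole change, since the lowest median over quantile normalization and median centring was 0.73 (highest adjusted p 2.05e-21) and over 6 arrays left out in turn 0.67 (highest adjusted p 9.27e-19), beside 0.71 as reported. If the list followed the level of ID1, ID3 and ID4 in step, BMP2 on top of DM, which raised these 3 genes again, would have lowered it. Its median in BMP2+DM against DM was 0.0610 (95% interval over members -0.02 to 0.11). At 24 h the list thus did not fall in step with the rise of these 3 genes, which was found and tested on the same data. With both reagents ID3 and ID4 were still lower than PBS, at -1.33 and -0.75. A dependence that is not in step with their level was not tested. A link with other BMP-SMAD targets stays open, since BMP2 brought back 22.8% of the fall in SMAD9 and 16.0% in SMAD7. One compound at 1 dose leaves open whether others would do the same.

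Hypoxia and glycolysis genes were lower with BMP2 alone, with DM alone and with both, but with an estimated correlation the call held for BMP2 alone (adjusted p = 0.0302) and was lost for DM (0.0719) and for both (0.17). Neither scaling nor 1 array accounts for the whole fall with BMP2 alone. The smallest median for BMP2 against PBS was -0.42 over the scalings (highest adjusted p 4.16e-15) and -0.31 over the arrays left out in turn (highest adjusted p 1.89e-10). These p-values are from camera at the preset correlation, and no array was left out with an estimated one. That the PBS arrays stood apart from all others stays open and cannot be told apart from effects of the reagents, because BMP2+DM against BMP2, which uses no PBS array, had a median of 0.20 with a 95% interval over members of -0.01 to 0.59. CXCR4 shows the same layout, with a signal of 1241 in PBS, 144 with BMP2, 266 with DM and 345 with both. The interaction uses the PBS arrays as well, so for this list and CXCR4 it is open to the same explanation. Oxygen or glucose in the cultures was not recorded in the labels, so no biological explanation other than the reagents was tested.

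DM was called in more genes with BMP2 present (919) than without (453). Noise in the BMP2 arrays cannot be told apart from a larger effect: with array weights the counts were 617 and 977, a ratio of 1.58, but over 12 arrays left out in turn the weighted ratio ran from 0.637 to 3.94. Whether 1 array decides it is open as well: the lowest unweighted ratio was 1.39, without BMP2 replicate 1 (497 and 690), but the weighted ratio was 0.637 without BMP2 replicate 3 (573 and 365) and 0.988 without BMP2 replicate 1. A count past a threshold does not show that effects differ, and the interaction test called 15 genes.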

How the results depend on the processing

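The omission of arrays for list counts and for the slope, and the scalings and the offset for list counts, were chosen after the data were seen; the other alternatives were planned, and except where said below the cause of a change was not tested.

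Of 150 named values called, none changed sign when any 1 array of its comparison was omitted and 83 stayed called in every omission; 0 of the 10 called interaction values did. Over 12 other alternatives 1480 of 1751 values kept direction and call, 267 kept direction only, and 4 reversed, all with the mean of a gene's probe sets: SMAD9 at -0.0718 in BMP2 against PBS, P4HA1 at 0.15 in DM against PBS, and HSPD1 at 0.14 and IL1A at -0.59 in BMP2+DM against BMP2. The filters, every probe set, the variance models, only the groups compared and the block follow the same probe set and cannot change its fitted value. Direction was therefore fixed in these alternatives, and only the call could change. Of 72 called values with other probe sets above the filter, 12 had at least 1 of opposite sign (APLP2, BIRC5, ID4, IDI1, SF3B1, SLC35C1, SMAD6, TPM1). SMAD9, P4HA1, HSPD1 and IL1A were not among these genes. Their reversals therefore rest on probe sets below the filter, which the mean of a gene's probe sets takes in. Of the 38 list calls, 34 held over 16 alternatives (the scalings, the offset, the block and each array omitted) and all 38 kept their sign. The block, or omitting an array outside the comparison, cannot change a list's median, so the sign was fixed there. The 16 leave out the estimated correlation, the mean of a gene's probe sets and the variance model without a trend. With an estimated correlation fewer lists were called in each comparison.

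In the order BMP2 against PBS, DM against PBS, BMP2+DM against BMP2, BMP2+DM against DM, interaction and BMP2+DM against PBS, the mean of a gene's probe sets called 10, 104, 275, 1, 1 and 119 genes, and the variance model without a trend 12, 227, 455, 2, 1 and 238. Median centring called 50, 234, 517, 6, 2 and 221. A 2-fold threshold, which can only remove genes, left 25, 84, 153, 3, 12 and 73. Every probe set gave 13 for BMP2+DM against DM, 6 for the interaction and 958 for BMP2+DM against PBS; array weights gave 14, 31 and 828. The brightest 30% of probe sets gave 26 interaction genes, and only the groups compared gave 41 for BMP2 against PBS.

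The median of the BMP-SMAD list in BMP2+DM against PBS, -0.16 with an unadjusted camera p of 0.047, had p = 0.341 with an estimated correlation (-0.16), -0.15 without the filter (p = 0.0604), -0.15 with every probe set (p = 0.114) and 0.0529, reversed, with the mean of a gene's probe sets (p = 0.489). With an estimated correlation 5 lists were called in DM against PBS, 0 in BMP2+DM against DM and 2 in BMP2+DM against PBS; log2 of the signal plus 32 gave 6 interaction lists where 3 are reported. The slope of the BMP2 effect with DM on that without was 0.0423 with every probe set.

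With 1 array of the comparison omitted, counts ran from 36 (PBS replicate 3) to 101 (BMP2 replicate 2) in BMP2 against PBS, 252 (PBS replicate 3) to 347 in DM against PBS, 553 (BMP2+DM replicate 2) to 887 in BMP2+DM against BMP2, 3 (DM replicate 2) to 21 (BMP2+DM replicate 1) in BMP2+DM against DM, 0 (PBS replicate 3) to 42 (BMP2 replicate 2) for the interaction, and 269 (BMP2+DM replicate 3) to 409 in BMP2+DM against PBS. The list median in BMP2+DM against PBS ran from -0.21 (PBS replicate 1) to -0.07 (PBS replicate 3), interaction lists from 3 to 7 (BMP2+DM replicate 3), lists in BMP2+DM against DM from 1 (BMP2+DM replicate 3) to 3, and the slope from 0.0406 (BMP2 replicate 2) to 0.270 (PBS replicate 3).

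A replicate block gave 61, 399, 858, 6, 8 and 479 genes in the same order. Replicate numbers paired the arrays weakly at most: residuals of the same number correlated at -0.026 to 0.059 over 18 pairs, beside -0.070 to 0.047 for other pairs. Yet 8 of the 12 arrays were closest to their own number, so a weak pairing stays open.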

Other observations

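All lists in this part were chosen after the results had been seen, and their p-values are not adjusted.

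Enzymes that charge cytosolic tRNA rose with DM as a group. Of 17 measured cytosolic aminoacyl-tRNA synthetase genes, 9 rose and none fell in DM against PBS by limma, with WARS1 at 1.46, SARS1 at 1.21, GARS1 at 1.03 and CARS1 at 1.02. The median was 0.39 (0.42 with quantile normalization; 0.45 with median centring, where 7 were called), with a camera p of 1.46e-13 and p = 0.00247 with an estimated correlation. In BMP2+DM against BMP2 9 of the 17 rose as well, or 5 with median centring. Of 15 measured mitochondrial synthetase genes 0 were called by limma in DM against PBS (1 at an unadjusted p under 0.05), with a median of 0.06 and a camera p of 0.595. In BMP2+DM against BMP2 1 of the 15 was called higher (0 with median centring) and 4 were higher at an unadjusted p under 0.05. The median there was 0.08, with a camera p of 0.207. In DM against PBS the medians of the cytosolic and mitochondrial lists differed by 0.33, with p = 0.00183 in a two-sided permutation test with 100000 permutations of genes between the lists, which are not independent replicates. Of 7 measured serine and one-carbon enzymes 4 rose, but 3 of these, PHGDH, PSAT1 and MTHFD2 (0.71), also belong to the ATF4 list, so no test of this list is given. Of the 4 other members, SHMT2 rose, by 0.97, and their median was 0.25.

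Metallothioneins, small proteins that bind zinc and copper, moved the other way. Of 7 measured genes 3 fell in DM against PBS and none rose, MT1H by 1.19, MT1X by 0.63 and MT2A by 0.57 on the log2 scale. Positive values, not called, were found for 2 of the 7. The median was -0.50 (-0.51 with quantile normalization, -0.44 with median centring), with a camera p of 1.39e-06 and p = 0.00171 with an estimated correlation. MT1H was higher by 0.70 in BMP2+DM against DM, a call lost with median centring, where 0 of the 7 were called. The sequences of this family are so alike that its probe sets can cross-hybridise, so the values of single members are uncertain. Members may then not be separate measures, which the list's camera p at the preset correlation does not allow for.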
